A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

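Expression and splicing were measured by RNA sequencing in 4 yeast strains with 1 library each. Per the labels' protocols, cells were grown in YPD to mid-log phase, RNA was extracted with hot phenol and treated with DNase, and libraries were made with the TruSeq V2 kit, which does not mark strand. Reads from a gene and from a partner on the opposite strand therefore cannot be told apart. Per the submitters' processing notes the genome build was sacCer3 and the tools included CASAVA and STAR 2.4.0, with no role stated. The counting tool, the annotation and any read filter are not given in the sources used here.

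Gene expression was deposited as RPKM, reads per kilobase of gene scaled to library size, in a column for each strain. Splicing efficiency was deposited as a fraction from 0 to below 1 for each intron or isoform, and the authors' formula is not stated. Cells without a number in the splicing table, 1 for WT, 4 for snf2∆, 1 for ume6∆ and 3 for the double deletion, have no value here. The snf2∆ column was treated as the same fraction as the others. Of the lines of RPKM values, 3 named with a single letter name no gene and were left out; they held between 0.0811% and 0.221% of each library's summed RPKM. This left 6659 genes, of which 5986 matched the R64 reference annotation by systematic name or symbol and 673 did not. R64 is the assembly behind sacCer3, and all positions are from it. No mitochondrially encoded gene of the fixed list was measured (0 of 8), so that list is not analysed here.

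RPKM multiplied by the annotated gene length came out as whole multiples of a fixed step in each library. With a tolerance of 0.05 reads, 99.5% to 99.6% of values above 0 were whole, so reads per gene were recovered. The step gives the number of reads each library was scaled to, 27.7, 25.7, 30.2 and 17.4 M for WT, snf2∆, ume6∆ and the double deletion, and 26.7, 24.8, 28.6 and 16.7 M reads fell in the matched genes. For genes with introns, 99.3% of values were whole with the length from start to end of the gene and 7.04% to 14.1% with the exon length. The RPKM of such genes was therefore scaled by the length from start to end, and whether intron reads were counted is not known. A floor of 3 reads corresponds to 0.0995 to 0.172 RPKM for a gene of 1 kb. The intervals on RPKM ratios are exact 95% Clopper-Pearson intervals from the recovered reads, and both intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules.

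Changes were computed as differences of log2(RPKM + 1) for genes with a mean of at least 1 RPKM over the 4 libraries, which kept 6520 genes. A gene was counted as higher or lower at 2-fold. No test across replicates was possible. Of 5986 simulated genes with counting noise only, 98.0% to 100% of those changed 3-fold were called in the right direction over the 5 comparisons, 100 genes at a time, and 0.02% to 0.14% of unchanged genes were called. Of 40 random lists drawn from each simulated comparison, between 1 and 7 fell outside the central 95%; 7 was more than expected, so a larger check with 1000 lists was added after that result was seen, and it gave 4.1% to 7.4%. This simulation holds no variation between cultures.

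The all-gene medians of the log2 changes were -0.11 for snf2∆ over WT, -0.30 for ume6∆ over WT, 0.06 for the double deletion over WT, 0.35 for the double deletion over ume6∆ and 0.14 for the double deletion over snf2∆. Scaling by the median ratio to the geometric mean, tried as an alternative, brought them to between -0.01 and 0.000535. A list's median is therefore given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Percentiles moved with such scaling, but no list crossed the bounds of the central 95%. In all, 28 of 29 lists, fixed before the data were examined, had measured members. Of 140 pairs of list and comparison, 72 fell outside the central 95% of random lists, where 7 would for lists of random genes. The pairs are not independent, since lists share genes, members of a list can vary together and the 5 comparisons use 4 libraries. A percentile describes these libraries and does not carry to other cultures.

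Genes are named by a rule fixed before the data were examined. It took the deleted genes, the 10 largest rises and 10 largest falls for each single deletion against WT, and 5 and 5 for the other comparisons, among genes with a mean of at least 10 RPKM and a standard symbol. It also took 2 to 4 members of each list with the largest changes, every measured intron of a meiotic gene, and the introns with the largest changes among hosts with at least 10 RPKM. HOP1, IME2, MER1, REC107, SPO1, NDT80 and HSP78 in places, AMA1 in snf2∆, and the examples shared between backgrounds were chosen after their values were seen. So was the account of a-cell and alpha-cell genes, MET17 and LYS2 across all 4 libraries, although the rule had picked the genes it names in single comparisons. Introns were compared by the difference of efficiency, with lists of introns matched on host expression in 8 bins. Random lists could hold a list's own members. Percentiles are therefore hard to read for lists with a large part of all introns, such as ribosomal protein introns and other introns.

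Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 10 RPKM, median ratio scaling, equal totals outside ribosomal protein genes, thresholds of 1.5 and 4-fold, and a counting interval that excludes no change. For introns they were a host filter, introns outside ribosomal protein genes, log2 ratios and means. Removal of mating-type and marker genes, of small nucleolar and nuclear RNAs, and of meiotic introns was added after seeing the data, as were the counts within lists under median ratio scaling and the split of introns by whether they stood at 0. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with figures from matplotlib 3.10.9.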

Results

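RNA depleted of ribosomal RNA was sequenced from 4 haploid strains of budding yeast (Saccharomyces cerevisiae, BY4741/2 background) grown in rich medium with glucose to mid-log phase. The strains were wild type (WT), snf2∆, ume6∆ and the double deletion ume6∆snf2∆, with 1 library each. Snf2 is the ATPase of Swi/Snf, a complex that moves and evicts nucleosomes. Ume6 is a DNA-binding repressor that keeps early meiotic genes silent in growing cells. Expression was given as RPKM for 6659 genes, and splicing efficiency as a fraction for 298 introns or isoforms of 281 genes. The RPKM values were scaled to 27.7 M reads for WT, 25.7 M for snf2∆, 30.2 M for ume6∆ and 17.4 M for the double deletion. The median gene had 1446, 1204.5, 1259 and 936 recovered reads in the same order. With 1 library per strain no difference has a replicate check, so sizes are given without p-values, and each 95% interval covers counting error only. Log2 changes are differences of log2(RPKM + 1), which understate the change of low genes, while ratios and folds against a floor of reads are of RPKM. A change here means at least 2-fold on that scale, in these libraries.

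The deleted genes followed the strain names. SNF2 (YOR290C, chromosome XV, 855147 to 860258) had 67.9 RPKM in WT and 36.9 in ume6∆, against 0.107 in snf2∆ and 0.157 in the double deletion. UME6 (YDR207C, chromosome IV, 865012 to 867522) had 34.6 RPKM in WT and 19.6 in snf2∆. It had 0.0132 RPKM, or 1 read, in ume6∆ (ratio to WT 0.000382, interval 9.66e-06 to 0.00213) and 0.137 RPKM, or 6 reads, in the double deletion. Genes of the mating types also separated the libraries, along the same line as SNF2. STE2, the receptor for alpha-factor made by a cells, had 416 RPKM in WT and 296 in ume6∆ but 6.29 in snf2∆ and 15.7 in the double deletion. STE3, the receptor of alpha cells, had 3.60, 3.80, 165 and 151 RPKM in WT, ume6∆, snf2∆ and the double deletion. HMRA1, whose sequence is shared with the a copy of the mating-type locus, had 702 reads in WT, 544 in ume6∆ and 0 in both libraries without SNF2. A pair of nutritional genes set the double deletion apart. MET17, which makes homocysteine, had 2350.2 RPKM there and 0.817 to 1.12 in the other libraries, and LYS2, of lysine synthesis, had 0.385 RPKM there and 91.0 to 303 elsewhere. Both were on the fixed list of strain marker genes. Their differences may reflect the markers carried by each strain and are not read as effects of Snf2 or Ume6. Expression of a-cell and alpha-cell genes therefore differed wherever a library without SNF2 is compared with a library that has it, and MET17 and LYS2 differed wherever the double deletion is compared.

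**Figure D1:**
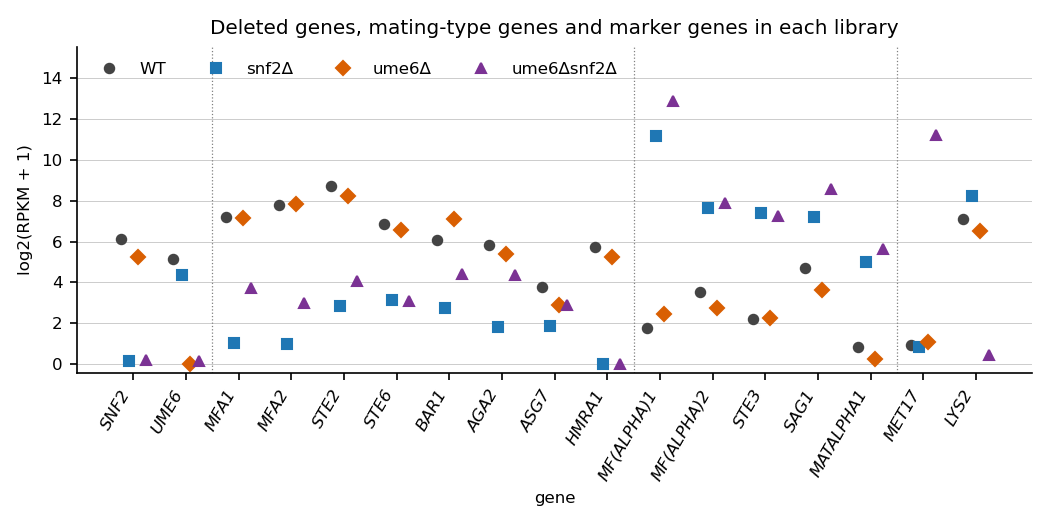
Expression of the deleted genes, of a-cell genes with HMRA1, of alpha-cell genes with MATALPHA1, and of MET17 and LYS2, separated by dotted lines; the y axis is log2(RPKM + 1) and each symbol is 1 library. STE2 lies at 416 and 296 RPKM in WT and ume6∆ and at 6.29 and 15.7 in snf2∆ and the double deletion, and STE3 shows the opposite order.

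The comparison of snf2∆ with WT addressed which genes differ without Snf2, in libraries that also differ in a-cell and alpha-cell genes. Many genes for amino acid synthesis were higher, while many genes listed for stress and most for phosphate uptake and cell separation were lower. MET6 (YER091C, chromosome V, 339864 to 342167), the methionine synthase, went from 214 to 2688 RPKM, a log2 change of 3.64. SER3 (YER081W, chromosome V, 322686 to 324095), the first enzyme of serine synthesis, went from 103 to 1301 RPKM (log2 3.64), and LEU1, of leucine synthesis, from 290.0 to 2734 (log2 3.23). SER3 overlaps SRG1 on the same strand, so its value may include reads of SRG1. HSP12 (YFL014W, chromosome VI, 107256 to 107585), a small heat shock protein, went from 822 to 4.96 RPKM, and the small heat shock protein gene HSP26 from 297 to 7.31. Among all 6520 genes kept, 216 were higher and 519 lower, and the median gene changed by -0.11. Median ratio scaling gave 251 higher and 443 lower.

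Besides the amino acid genes, the 10 largest rises held CAR1, the arginase that starts arginine breakdown, at 18.1 RPKM in WT and 273 in snf2∆. The remainder were alpha-cell genes, namely MF(ALPHA)1 and MF(ALPHA)2, which encode the alpha-factor pheromone, STE3, AFB1, MATALPHA1 and its silent copy HMLALPHA1. MF(ALPHA)1 went from 2.46 to 2308 RPKM, a ratio of 937 with an interval of 670.4 to 1353. MATALPHA1 and HMLALPHA1 share their sequence, so their reads cannot be told apart. The 10 largest falls likewise mixed a-cell genes with metabolic and stress genes. MFA1 and MFA2, which encode a-factor, had 3 reads each in snf2∆, at ratios of 0.00733 (interval 0.00151 to 0.0216) and 0.00453 (interval 0.000933 to 0.0133). HMRA1 was at least 217-fold lower, counted against a floor of 3 reads. ARO9, an aromatic aminotransferase, went from 62.5 to 1.77 RPKM, SPL2, a regulator of phosphate transport, from 39.6 to 0.785, YRO2 from 218 to 6.93 and MNC1 from 274 to 6.79.

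Of 36 amino acid synthesis genes 18 were at least 2-fold higher and 0 lower, and their median change of 0.94 exceeded that of all 10000 random lists matched on expression. ARG3, of arginine synthesis, went from 56.6 to 308 RPKM, and SER33, a second copy of the SER3 enzyme, from 69.7 to 276. In the list for sulfur amino acids 15 of 26 genes were higher and 0 lower, with a median of 1.49. SUL2, a sulfate permease, went from 15.9 to 143 RPKM and MET13 from 34.7 to 288. The stress response list had 22 of 36 genes lower and 1 higher, with a median of -1.16 that lay below all random lists, and 18 lower with median ratio scaling. Examples were YGP1, a secreted glycoprotein, from 529 to 22.9 RPKM and GPH1, glycogen phosphorylase, from 137 to 7.68. HSP78, a mitochondrial chaperone, was the 1 gene of that list that was higher, at 47.1 and 96.5 RPKM.

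Phosphate starvation genes were lower in 12 of 17 cases and higher in 0 (median -1.56). PHO84 (YML123C, chromosome XIII, 24037 to 25800), the high-affinity phosphate transporter, went from 640.0 to 31.0 RPKM and PHO89, a sodium-coupled transporter, from 40.3 to 2.71. PHO84 overlaps a gene on the opposite strand, whose reads cannot be told apart. Genes that separate daughter cells from mothers were lower in 8 of 10 cases (median -1.61), among them DSE1 at 429.8 and 80.6 RPKM and EGT2 at 288 and 59.4. Of 45 genes for respiration and the citric acid cycle, 7 were lower and 0 higher (median -0.62), including CYT1, cytochrome c1, at 104 and 31.5 RPKM. The 3 medians lay below all 10000 random lists. Among 8 genes reported earlier to need Swi/Snf, HO, the mating-type switching endonuclease, had 22.8 and 1.86 RPKM, INO1, the inositol phosphate synthase, had 25.3 and 3.21, and PHO84 was lower as given for the phosphate genes. SUC2, the invertase gene of the same list, had 51.5 and 98.5 RPKM, and the list median of -0.36 fell within the central 95% of random lists. Cells were grown in rich medium with glucose only. Whether these genes need Swi/Snf under other growth conditions was therefore not tested. Ribosomal protein genes had a median of 0.34 with 3 of 137 higher, above 99.99% of random lists, and ribosome biogenesis genes a median of -0.31 at percentile 0.05. Early meiotic genes had a median of -0.43, with 3 of 36 lower, at percentile 0.43. NDJ1, a telomere protein of meiosis, had 18.5 and 2.17 RPKM and MER1, a meiotic splicing activator, 29.8 and 8.49. With a pseudocount of 5 the early meiotic list moved to percentile 5.41, inside the central range.

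The comparison of ume6∆ with WT addressed which genes differ without the Ume6 repressor. Most early meiotic genes and most iron uptake genes were higher, and most stress genes were lower. Ribosomal protein genes had a raised list median, and genes for respiration and amino acid synthesis a lowered list median, with counts that depended on the scaling. HOP1 (YIL072W, chromosome IX, 226602 to 228419), a component of meiotic chromosome axes, went from 7.14 to 62.2 RPKM, a log2 change of 2.96. SAE3 (YHR079C-A, chromosome VIII, 262192 to 262553), a cofactor of the meiotic recombinase Dmc1, went from 5 reads to 1039 reads (ratio 191, interval 81.6 to 589). INO1 (YJL153C, chromosome X, 134332 to 135933) went from 25.3 to 955 RPKM (log2 5.18). CMK2 (YOL016C, chromosome XV, 294777 to 296120), a calmodulin-dependent kinase, went from 958 to 26.4 RPKM (log2 -5.13).

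In all, 299 genes were higher and 989 lower, and the median gene changed by -0.30. Scaling each library by the median ratio, which brings that median to -0.00480, gave 573 higher and 546 lower, so the balance of directions depended on the scaling. List medians below are therefore given with their place among random lists matched on expression. That place can differ from a reading against the median of all genes.

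Of 36 early meiotic genes 26 were at least 2-fold higher and 0 lower, with a median of 1.86 that exceeded all 10000 random lists. Besides SAE3, the largest changes were in HOP2, of homolog pairing (0.882 to 62.2 RPKM), HED1 (1.99 to 94.8), and ECM11, of the synaptonemal complex. ECM11 had 2 reads in WT and 551 in ume6∆ (ratio 253, interval 69.8 to 2096). REC107 had 26.4 and 14.6 RPKM and MER1 29.8 and 15.3, so these early meiotic genes were not among those that were higher. In contrast, 4 of 31 middle and late sporulation genes were higher and 9 lower, with a median of -0.32 within the central 95% of random lists. SPO1, a phospholipase homolog, had 11.5 and 29.8 RPKM, and NDT80, the activator of the middle genes, had 14.9 and 5.95. Of the 10 genes listed as Ume6, its corepressors and regulators of meiotic entry, 0 were higher and 4 lower, UME6 itself among them (median -0.87, percentile 1.49). Other genes among the 10 largest rises were PHO92, a reader of methylated RNA (0.587 to 60.2 RPKM), RNP1 (1.83 to 76.3), FIT2, a cell wall protein that retains iron (7.34 to 187), LSO1 (0.767 to 37.7) and CWP1, a cell wall mannoprotein (10.1 to 228).

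Iron uptake genes were higher in 10 of 17 cases and lower in 1, with a median of 1.14 above all random lists. FET3, the ferroxidase, went from 39.1 to 334 RPKM, and TIS11, which promotes decay of iron-related messages, from 5.76 to 36.9. Ribosomal protein genes had a median of 0.85, with 39 of 137 higher and 0 lower, also above all random lists, and RPS24B had 439 and 1768 RPKM. With median ratio scaling 100 of the 137 were higher. The stress response list had 25 of 36 genes lower and 0 higher (median -1.51), including HSP26 (297 to 26.2 RPKM), SPI1 (159 to 14.7) and MSC1 (114 to 11.3). Respiration genes were lower in 24 of 45 cases and higher in 1 (median -1.03), with CYT1 at 104 and 23.5 RPKM and RIP1, the Rieske iron-sulfur protein, at 117 and 26.6. Amino acid synthesis genes were lower in 13 of 36 cases and higher in 1 (median -0.73), among them ARG5,6 at 190.5 and 50.1 RPKM. These 3 medians lay below all random lists. With median ratio scaling 19 stress genes, 15 respiration genes and 7 amino acid genes were lower. The sulfur amino acid list went the other way, with 10 of 26 genes higher and 1 lower (median 0.78), including MET3, ATP sulfurylase, at 40.4 and 313 RPKM. Of 17 nitrogen catabolism genes 2 were higher, CAR1 (18.1 to 266 RPKM) and CAR2 (24.2 to 236), and 3 lower, or 1 lower with median ratio scaling, with a median of -0.21 inside the central range. Phosphate starvation genes were lower in 7 of 17 cases and higher in 0 (median -0.81, percentile 0.38), among them PHO84 (640.0 to 117). Genes for daughter cell separation were lower in 3 of 10 cases and higher in 0 (median -0.78, percentile 0.52). With median ratio scaling 4 phosphate genes and 1 separation gene were lower.

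The 10 largest falls had few members in the fixed lists. They were CMK2, MNC1 (274 to 9.24 RPKM), HOR7 (2212 to 118), GSC2, a glucan synthase subunit (712 to 37.9), PHO89 (40.3 to 1.71), DIA1 (243 to 17.0), PLB1, phospholipase B (428 to 31.0), RTC3 (105 to 7.50), RCR1 (207 to 16.4) and RCN2, a regulator of calcineurin (262 to 21.6). DIA1 overlaps a gene on the opposite strand, and the library kit does not mark strand.

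**Figure D2:**
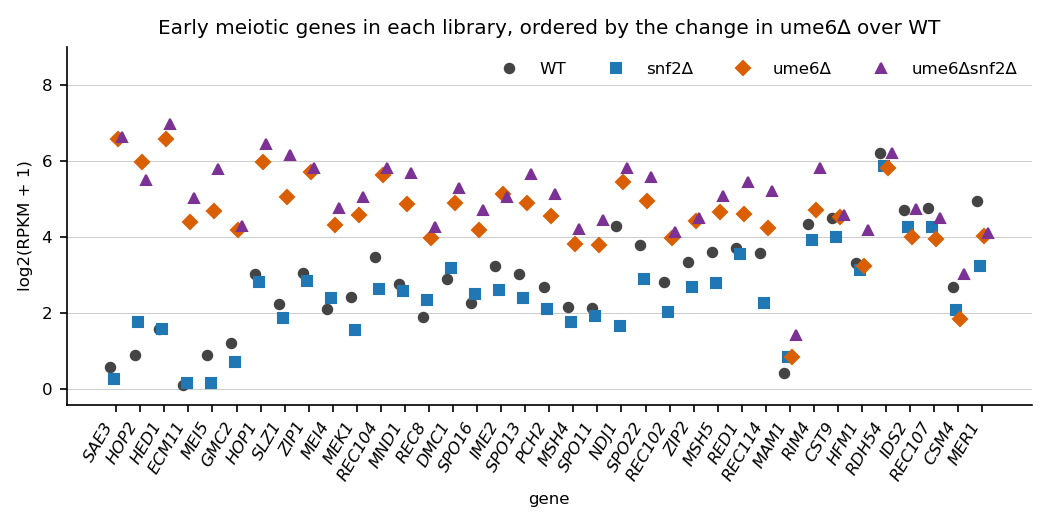
Expression of the early meiotic genes as log2(RPKM + 1) on the y axis, with genes on the x axis ordered by the change in ume6∆ over WT and each symbol 1 library. HOP1, for example, had 7.14 RPKM in WT, 6.11 in snf2∆, 62.2 in ume6∆ and 86.1 in the double deletion.

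Removing both proteins gave 676 genes higher and 650 lower than WT, with a median change of 0.06, or 620 higher and 700 lower with median ratio scaling. Early meiotic genes were again higher, in 29 of 36 cases with 0 lower and a median of 2.33. HED1 went from 1.99 to 126 RPKM (ratio 63.2, interval 43.2 to 96.4) and SAE3 from 0.498 to 98.8. Stress response genes were lower in 23 of 36 cases (median -1.33), phosphate genes in 11 of 17 (median -1.30) and daughter separation genes in 7 of 10 (median -1.50). HSP12 went from 822 to 16.5 RPKM, HOR7 from 2212 to 54.8 and HXT4, a hexose transporter, from 314 to 8.12. MF(ALPHA)1 was among the largest rises at 7498 RPKM, with MET17 and DPA10 (0.956 to 75.6 RPKM), and LYS2 and HMRA1 were among the largest falls. HMRA1 was at least 147-fold lower against the floor of 3 reads. Nitrogen catabolism genes were higher in 8 of 17 cases and lower in 1 (median 0.95), with CAR1 at 566 RPKM and DAL1, allantoinase, at 5.84 and 37.4. Comparisons that share the WT library also share its chance values, so their overlap was not counted.

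The double deletion and ume6∆ were compared as strains without and with Snf2 in which meiotic genes were already expressed, and which also differ in a-cell and alpha-cell genes, MET17 and LYS2. Early meiotic genes did not stand apart, with 4 of 36 higher, 0 lower and a median of 0.45 against 0.35 for all genes (percentile 39.3). HOP1 had 62.2 and 86.1 RPKM, IME2, the meiotic kinase, 34.0 and 32.0, and MEI5, partner of SAE3, 24.6 and 54.6. Amino acid synthesis genes were higher in 20 of 36 cases and lower in 1 (median 1.13), and nitrogen catabolism genes in 10 of 17 (median 1.09). With median ratio scaling 15 amino acid genes and 4 nitrogen genes were higher. Examples were SER3 (44.6 to 1295 RPKM), ARG5,6 (50.1 to 516) and GAP1, the general amino acid permease (7.95 to 39.7). Ribosomal protein genes had a median of -0.56, with 16 of 137 lower and 0 higher, below all 10000 random lists, and iron uptake genes a median of -0.80 with 7 of 17 lower. With median ratio scaling 56 and 9 were lower, and 0 early meiotic genes were higher. Stress response genes had a median of 0.04, below that of all genes, at percentile 0.21. RPS28B went from 391 to 102 RPKM and SIT1, a siderophore transporter, from 79.2 to 11.3.

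Of the 8 genes reported earlier to need Swi/Snf, 4 were lower in that comparison and 0 higher (median -0.64, percentile 0.03). HO went from 63.7 to 7.20 RPKM, INO1 from 955 to 300.0, ADH2, of ethanol use, from 168 to 65.8 and PHO84 from 117 to 47.2. In total 724 genes were higher and 225 lower, with an all-gene median of 0.35. Median ratio scaling gave 331 higher and 433 lower, so the direction of the majority turned with the scaling. The largest rises were MF(ALPHA)1, MET17, HMLALPHA1, MATALPHA1 and MF(ALPHA)2, and the largest falls LYS2, HMRA1, MFA2 and the small nucleolar RNAs SNR36 (279 to 5.05 RPKM) and SNR49 (1665 to 44.9). HMRA1 was at least 105-fold lower.

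The double deletion and snf2∆ were compared as strains without and with Ume6 in which Snf2 was already missing, and which also differ in MET17 and LYS2. Early meiotic genes were higher in 30 of 36 cases and lower in 0, with a median of 2.48 above all random lists. MEI5 went from 2 to 637 reads (ratio 469, interval 129 to 3881), NDJ1 from 2.17 to 55.8 RPKM and HOP1 from 6.11 to 86.1. INO1 went from 3.21 to 300.0 RPKM (log2 6.16) and LSO1 from 0 to 221 reads. Stress response genes had a median of 0.12 against 0.14 for all genes (percentile 39.7), and phosphate genes a median of 0.37. Sulfur amino acid genes were lower in 5 of 26 cases and higher in 0 (median -0.45), including SUL1, a sulfate permease, at 56.4 and 18.6 RPKM. In total 530 genes were higher and 155 lower, or 394 and 234 with median ratio scaling. Although both strains had alpha-type expression, 6 of 7 a-cell genes were higher in the double deletion, or 5 with median ratio scaling (median 1.70), among them BAR1, a protease that degrades alpha-factor, at 5.68 and 20.7 RPKM. Of 4 alpha-cell genes 2 were higher (median 0.80), including MF(ALPHA)1 at 2308 and 7498 RPKM. Both medians lay above the central 95% of random lists. MET17 and SAE3, with 2 and 623 reads (ratio 459, interval 126 to 3796), were the other large rises, and LYS2, SNR36, SNR49, SNR80 and SNR37 the largest falls. SNR80 had 1 read in the double deletion against 91 in snf2∆ (ratio 0.0162, interval 0.000405 to 0.0925).

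**Figure D3:**
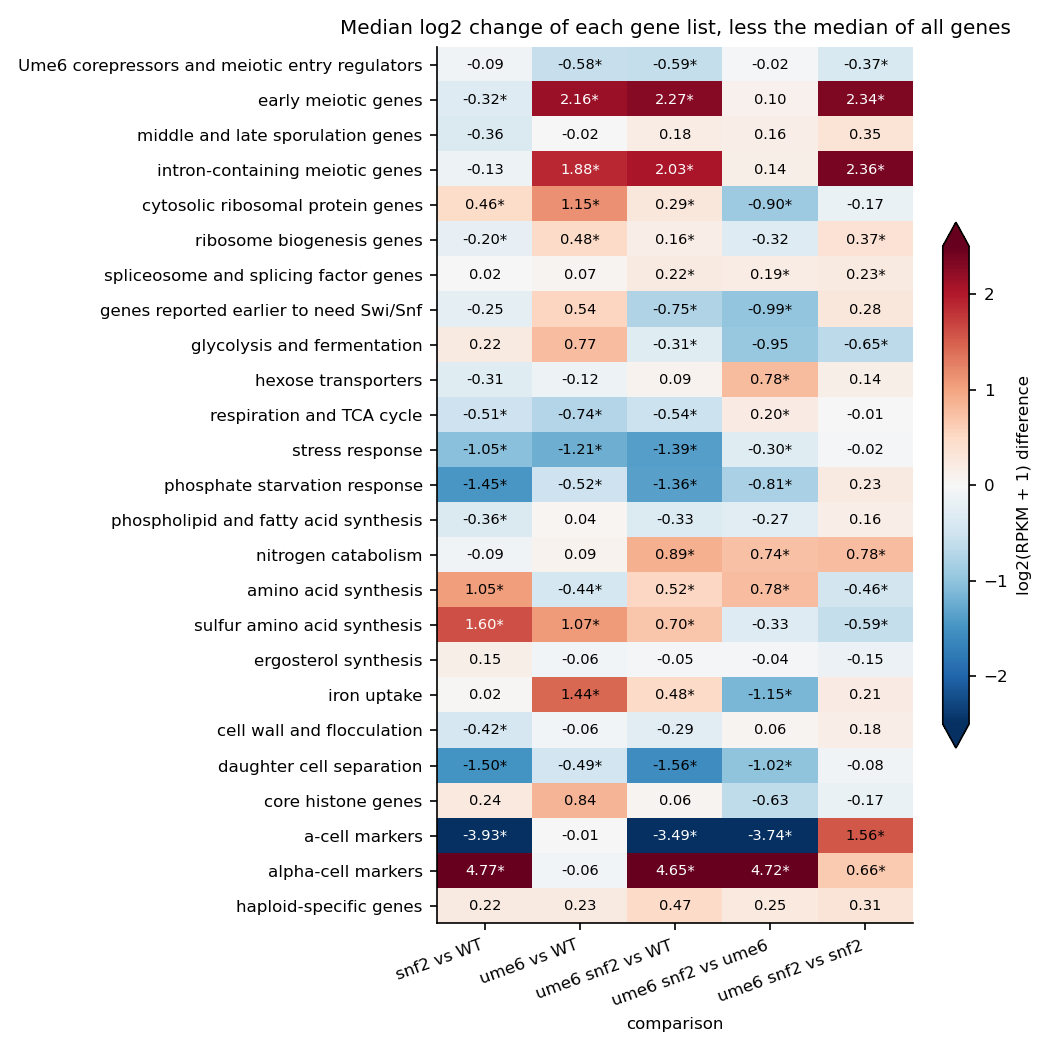
Median log2(RPKM + 1) change of each gene list, on the y axis, less the median of all genes, in each comparison on the x axis; red is higher, blue is lower, and an asterisk marks a median outside the central 95% of 10000 random lists. Early meiotic genes are red in the 3 comparisons that remove Ume6, with list medians of 1.86, 2.33 and 2.48 before subtraction.

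Differences that went with Snf2 loss were compared between strains with and without Ume6, using snf2∆ over WT and the double deletion over ume6∆, which have no library in common. In these comparisons 111 genes were higher both times, where independent lists would share 24.0, and 84 were lower both times, where independent lists would share 17.9. Median ratio scaling gave 91 higher and 118 lower, so the balance of directions depended on the scaling. Alpha-cell genes, SER3, LEU1, MET13 and ARG3 were among the former. The latter included a-cell genes, HSP12, HO, SED1, a cell wall protein (2349 and 231 RPKM in WT and snf2∆, 1376 and 204 in ume6∆ and the double deletion), and CHO2, of phosphatidylcholine synthesis (220.1, 35.2, 187 and 17.3 in the same order). Across 6520 genes the log2 changes had a Pearson r of 0.37 and a Spearman rho of 0.22, where genes are not independent replicates. Both comparisons have the same direction of difference in a-cell and alpha-cell genes, and the shared counts were not recomputed without them.

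Ume6 loss was treated the same way, with ume6∆ over WT and the double deletion over snf2∆. Here 151 genes were higher both times against 24.3 for independent lists, and 61 were lower both times against 23.5, or 176 and 61 with median ratio scaling. Genes higher in both included SAE3, PHO92, INO1, HED1, ECM11, SIP4, an activator of gluconeogenic genes (4.93 to 79.8 and 5.23 to 52.7 RPKM), and ACS1, an acetyl-CoA synthetase (7.90 to 63.3 and 8.88 to 94.1). CIT2, the peroxisomal citrate synthase (258 to 29.0 and 175 to 41.0 RPKM), HIS4, of histidine synthesis (483 to 164 and 454 to 150), and TDH1, a glycolytic dehydrogenase (1473 to 258 and 318 to 114), were lower in both. MET17 and LYS2 differ within the second of these comparisons. Pearson r across genes was 0.40 and Spearman rho 0.32.

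Splicing efficiency had a median of 0.675 in WT, 0.701 in snf2∆, 0.693 in ume6∆ and 0.688 in the double deletion. In snf2∆ relative to WT the median intron changed by 0.0089, with 209 introns higher and 68 lower among 293, and with 33 higher and 7 lower by at least 0.1. Among hosts with a mean of at least 10 RPKM, the largest rises were in RPL22B (YFL034C-A, intron at chromosome VI, 64600 to 64920), a ribosomal protein gene, from 0.165 to 0.604, and in YBR062C, from 0.239 to 0.609. The largest falls were in DMC1, from 0.312 to 0, and YRA1, an export factor of messenger RNA, from 0.776 to 0.493. The depth behind each efficiency is unknown, so no interval can be given for an intron. Introns of ribosomal protein genes changed by a median of 0.0055, with 86 of 104 higher, and other introns outside the meiotic list by 0.0129, with 119 of 177 higher. Both medians lay within the central 95% of random lists of introns matched on host expression, as did that of 12 meiotic introns, at 0 with 4 higher and 2 lower. AMA1 went from 0 to 0.592 in snf2∆, on 55 and 48 host reads.

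In ume6∆ relative to WT the median over all introns was 0.000505, and that of 14 meiotic introns with a value was 0.166, at percentile 99.6 of random lists that were not matched on starting efficiency. Of these introns 9 stood at 0 in WT and could only stay or become higher. All 9 were higher, against 3 of 9 introns at 0 in WT outside the meiotic list. Of the 5 meiotic introns that started above 0, 4 were higher and 1 lower. The introns outside the list were not matched on the gain in host reads. More reads alone can turn a 0 into a higher value, so the contrast does not separate splicing from depth. SAE3 went from 0 to 0.577, SPO1 from 0 to 0.570, MEI4 from 0 to 0.389, REC114 from 0 to 0.325 and DMC1 from 0.312 to 0.685. REC102 had 0.332 and 0.434, PCH2 0 and 0.171, and MND1 0 and 0.0955. HOP2 had no value in WT, where its host gene had 19 reads, and 0.461 in ume6∆. SRC1 has 2 entries, of which the first fell by 0.136 and the second had 0.401 and 0.505. An efficiency of 0 in WT rested on few host reads for SAE3 (5 reads), but on 629 for SPO1 and 1071 for SPO22. RPL22B was higher than in the same WT library here too, at 0.666, and YRA1 lower, at 0.573. The double deletion had 0.593 and 0.516. With 1 WT library, a WT value apart from the others and an effect of each deletion cannot be told apart for these introns. Introns outside the ribosomal protein and meiotic lists had a median of 0.000449, below all but 0.855% of random lists. These were 178 of the 296 introns, with 91 higher and 81 lower, so that percentile does not show a fall.

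Introns controlled by Mer1, a splicing activator made in meiosis, were the group that differed most between ume6∆ and the double deletion. HFM1 (intron at chromosome VII, 31427 to 31578) went from 0.0803 to 0.488, SPO22 (chromosome IX, 225810 to 225899) from 0.277 to 0.674 and REC107 (chromosome X, 469184 to 469263) from 0.197 to 0.429. AMA1 (chromosome VII, 946328 to 946420), the remaining member, had 0.132 and 0.0855. The median change of the 4 introns was 0.315, at percentile 99.96 of random lists. Their host genes had 379 to 2708 reads in ume6∆ and 374 to 2463 in the double deletion. All 15 meiotic introns together had a median change of 0.0776, with 10 higher and 5 lower, at percentile 98.1. REC102 went from 0.434 to 0.696, the 2 entries of SRC1 from 0.173 to 0.395 and from 0.505 to 0.632, and SAE3, SPO1, MEI4, DMC1, HOP2, PCH2, MND1 and REC114 differed by less than 0.1. Over all 295 introns the median change was 0, with 144 higher and 145 lower, and ribosomal protein introns had a median of -0.0073 with 32 of 104 higher (percentile 1.12). ECM9 (0.484 to 0), RRT8 (0.360 to 0) and DTD1 (0.468 to 0.164) had the largest falls.

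The double deletion relative to WT combined these differences. The 14 meiotic introns with a value had a median change of 0.388, above all 10000 random lists. The 9 that stood at 0 in WT were all higher, against 4 of 9 such introns outside the meiotic list, again not matched on host reads. The 5 meiotic introns that started above 0 were also all higher. The median over all 294 introns was 0.0018. SPO22 went from 0 to 0.674, SAE3 from 0 to 0.672, SPO1 from 0 to 0.615 and HFM1 from 0 to 0.488. USV1 (0.571 to 0) and ECM9 (0.438 to 0) had the largest falls, with 173 and 78 host reads in the double deletion.

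**Figure D4:**
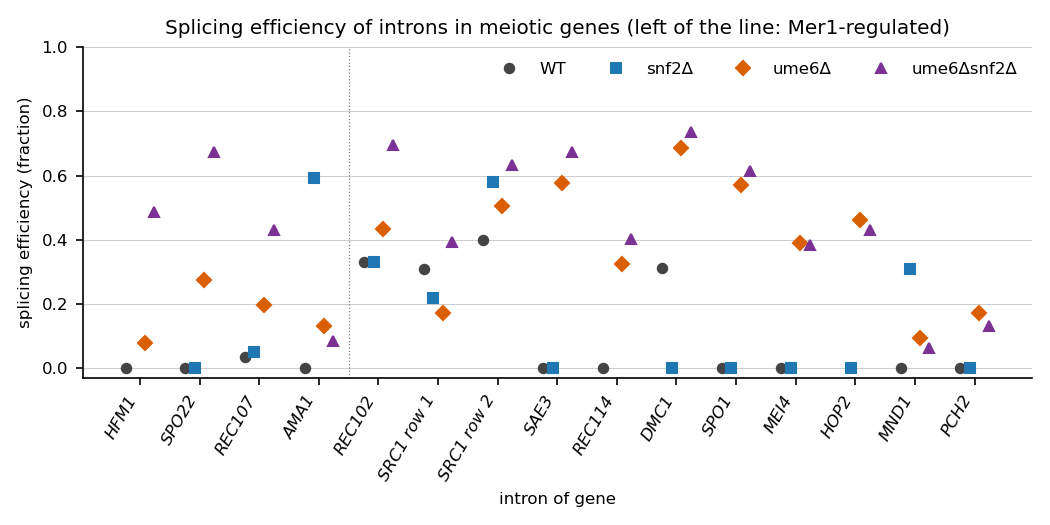
Splicing efficiency, as a fraction on the y axis, of each measured intron of a meiotic gene on the x axis, with introns controlled by Mer1 left of the dotted line and each symbol 1 library; a missing symbol means no value. HFM1, SPO22 and REC107 lie at 0.0803, 0.277 and 0.197 in ume6∆ and at 0.488, 0.674 and 0.429 in the double deletion.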

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

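The tests of explanations in this part were all chosen after the results were seen. The effects of a deletion were compared between its 2 backgrounds, and genes that went opposite ways were counted. With a single library per strain these differences were not tested. Snf2 loss had 6 genes higher over WT and lower over ume6∆, where independent lists would share 7.45. Among them were CWP1 (log2 1.12 and -4.60), FIT2 (1.39 and -2.28) and LYS2. LYS2 is a listed strain marker gene and is not read as an effect of Snf2. With Snf2 loss 30 genes were lower over WT and higher over ume6∆, against 57.6 for independent lists. They included PRB1, a vacuolar protease (-1.79 and 1.19), and SWI1, a Swi/Snf subunit (-1.03 and 1.02). Ume6 loss had 8 genes higher over WT and lower over snf2∆, against 7.11, including the small nucleolar RNA SNR49 (1.48 and -4.10) and the ribosomal protein gene RPS28B (1.25 and -1.05). It had 29 the other way, against 80.4, including HSP12 (-2.75 and 1.56) and TIR3, a cell wall mannoprotein (-1.27 and 2.28). With median ratio scaling the counts were 10 and 9 for Snf2 loss, against 16.7 and 22.5, and 22 and 12 for Ume6 loss, against 20.6 and 33.0. The commoner of the opposite directions thus turned with the scaling. With a pseudocount of 5 the counts were 3 and 6, and 5 and 7. The genes named here are from the main setting, and PRB1, SWI1 and TIR3 did not keep opposite 2-fold changes with median ratio scaling. Introns of ribosomal protein genes had a median change of 0.0055 for Snf2 loss over WT and of -0.0073 over ume6∆, a difference that was not tested either.

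Genes of a cells were low and genes of alpha cells high in both libraries without SNF2. A mislabelled sample is argued against by the deleted genes, whose RPKM where labelled deleted reached at most 0.700% of their lowest RPKM elsewhere. Silent mating-type copies turned on in a cells would repress haploid-specific genes, whose list median stood no lower than percentile 88.2 in either comparison. A difference in mating type of the strains, which the label BY4741/2 leaves open, may account for the pattern, since the lower of the 2 MATALPHA1 ratios, library without SNF2 over its partner, was 38.4 and HMRA1 had 0 reads there. Any effect of Snf2 itself on these genes was not tested.

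Stress response genes were lower in all 3 deletion libraries than in WT. Scaling of the RPKM values is argued against, since with median ratio scaling the list medians were -1.06, -1.22 and -1.38. Relative to all genes the largest difference in that median between deletion libraries was 0.303, lower in the double deletion than in ume6∆, at percentile 0.21 and so outside the central 95% of random lists. A WT library apart from the other 3, for example in growth state, and an effect of each deletion cannot be told apart, because there is only 1 WT library. Either could contribute to the 22, 25 and 23 lower genes among 36. Respiration and citric acid cycle genes also had medians below all random lists in each comparison with WT (-0.62, -1.03 and -0.48). Their median stood at percentile 61.0 in the double deletion over snf2∆ and at 99.99 over ume6∆. The same limit of 1 WT library applies to these genes.

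Of 4 introns controlled by Mer1, 3 had a higher splicing efficiency in the double deletion than in ume6∆. More MER1 transcript is argued against, because the MER1 ratio was 1.07 with a counting interval of 0.901 to 1.26. Chance among introns of like host expression is not excluded and cannot be told apart, because the percentile of 99.96 is the value that drew attention to these 4 introns and so is no separate test. Fewer ribosomal protein transcripts, with a list median of -0.56, could leave more splicing capacity, but cannot be told apart from other differences between these libraries: introns outside both lists had a median change of 0.00459 at percentile 87.9, inside the central range. Expression of a-cell and alpha-cell genes, MET17 and LYS2 differs between the same libraries, and whether this matters was not tested.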

How the results depend on the processing

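No paired test was run. The labels give no replicate numbers to pair libraries by, and each deletion was compared across its 2 backgrounds without a fit. With a single library per strain none could be left out. Removal of mating-type and marker genes, of small nucleolar and nuclear RNAs, or of meiotic introns was chosen after seeing the data. It moved no count of changed genes in a comparison by over 1.5 times and no splicing median beyond its resampling range. The counts shared between backgrounds were not recomputed without any of these genes, and they include the deleted genes SNF2 and UME6. A 4-fold threshold left 178 genes in snf2∆ over WT, 202 in ume6∆ over WT, 314 in the double deletion over WT, 148 over ume6∆ and 132 over snf2∆, by construction fewer. With a pseudocount of 5 the double deletion had 561 changed genes over ume6∆ and 432 over snf2∆, and the Ume6 effect shared between backgrounds had 138 genes; a higher pseudocount shrinks the change of low genes. At 1.5-fold the shared effects rose to 538 genes for Snf2 loss and 598 for Ume6 loss. Independent lists would then share 193 higher and 94.5 lower genes for Snf2 loss, and 142 and 161 for Ume6 loss. The mean over introns was 0.0284 for snf2∆ over WT, 0.0193 for ume6∆ over WT, 0.0228 for the double deletion over WT and 0.0032 over ume6∆. Introns outside ribosomal protein genes had medians of 0.0149 and 0.0065 in the last 2; the cause was not tested. The other 51 planned values for main results stayed within 1.5 times of the main count, or within the resampling range of the splicing median. Of the recomputed list percentiles 415 kept their side of the central 95%, 3 moved inside it and 2 moved outside. Median ratio scaling kept all 72 pairs of list and comparison outside the range on the same side. It turned the majority direction of changed genes in ume6∆ over WT (299 higher and 989 lower to 573 and 546). The same held for the double deletion over WT (676 and 650 to 620 and 700) and over ume6∆ (724 and 225 to 331 and 433). Requiring a counting interval that excludes no change left 645, 1154, 1150, 810 and 574 genes in the order above, among genes with recovered reads. Depth limits genes with few reads, such as UME6 in ume6∆ with 1 read, and the splicing efficiencies, whose depth is unknown.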

Other observations

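Further gene groups differed between these libraries. Hexose transporters had 5 of 18 genes lower and 0 higher in snf2∆, and 6 lower and 0 higher in ume6∆, with list medians of -0.42 and -0.42 inside the central 95% of random lists. HXT4, HXT7 and HXT6 had 314, 241 and 280.0 RPKM in WT against 23.3, 18.3 and 38.7 in snf2∆ and 30.5, 22.0 and 59.2 in ume6∆. HXT6 and HXT7 are near-identical copies, so their reads are uncertain. In the double deletion over ume6∆ 10 of 18 transporter genes were higher and 3 lower, or 4 and 3 with median ratio scaling (median 1.13, above all random lists), among them HXT17 at 5.14 and 18.4 RPKM. Glycolysis genes had a median of -0.50 in the double deletion over snf2∆ (percentile 0.05), with 2 of 17 lower and 0 higher. These were TDH1 at 318 and 114 RPKM and ENO1 at 1311 and 580.4. Over ume6∆ 8 of the 17 were lower and 1 higher, with a median of -0.60 against 0.35 for all genes. Its percentile of 3.44 was inside the central range of random lists matched on expression. Such lists may hold other highly expressed genes that were lower, such as ribosomal protein genes (median -0.56). That percentile therefore does not show that glycolysis genes changed like most genes. Phospholipid and fatty acid synthesis genes had a median of -0.48 in snf2∆ (percentile 0.21), with 6 of 18 lower and 0 higher, or 4 lower with median ratio scaling, among them FAS1, fatty acid synthase, at 736 and 244 RPKM. Cell wall and flocculation genes had a median of -0.54 there (percentile 0.17), with TIR3 at 44.8 and 5.44 RPKM.

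Spliceosome and splicing factor genes had a median of 0.28 in the double deletion over WT (percentile 99.92), with 12 of 88 higher and 1 lower. IST3 had 14.1 RPKM in WT, 32.3 in snf2∆, 27.7 in ume6∆ and 104 in the double deletion, and CWC21 had 91.2, 34.1, 38.0 and 81.7. Ergosterol synthesis genes, core histone genes and haploid-specific genes had no list median outside the central range in any of the 5 comparisons. The limit given for glycolysis genes may apply to core histone genes. Their median in the double deletion over ume6∆ was -0.28 against 0.35 for all genes, at percentile 39.4. ERG28 had 90.6 and 29.1 RPKM in WT and snf2∆, HTA2 180 and 303, and FAR1 46.4 and 55.1. Apart from SNF2 itself, the Swi/Snf subunit genes SWI1 (52.8, 25.3, 16.0 and 33.5 RPKM in WT, snf2∆, ume6∆ and the double deletion) and SNF5 (29.2, 31.9, 18.6 and 38.3) varied between libraries, and the median of that list stayed inside the central range in all 5 comparisons.

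In strains labelled as lacking histidine, uracil and leucine synthesis, LEU2 and URA3 had at most 0.10 and 0.09 RPKM in any library. HIS3 had 186, 310.4, 82.7 and 301. The RPKM of a gene does not show whether its transcript is intact, so the HIS3 values do not test the histidine label. The median RPKM of 76 small nucleolar and nuclear RNAs was 91.9 in WT, 41.2 in snf2∆, 62.0 in ume6∆ and 43.5 in the double deletion. SCR1, the RNA of the signal recognition particle, had 47704, 82650, 60025 and 79265 RPKM in the same order. The small nucleolar RNA SNR37 had 3411 RPKM in WT, 5326 in snf2∆, 5510.3 in ume6∆ and 367 in the double deletion, and SNR61 had 23, 22, 62 and 0 reads.

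Across introns the change in splicing efficiency and the log2 change of the host gene had a Pearson r of 0.41 and a Spearman rho of 0.20 for the double deletion over WT, and 0.11 and 0.16 for snf2∆ over WT, over 286 and 284 introns. Within the 104 ribosomal protein introns the Pearson r was 0.25 and 0.35, in the same order. Introns are not independent replicates. The change in snf2∆ over WT and in the double deletion over ume6∆ had a Pearson r of 0.00775 over 292 introns, with 97 introns higher and 29 lower in both, and 112 higher then lower and 38 lower then higher.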
